A study of Mus musculus with 10 samples.

How the data were processed

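Chromatin run-on and sequencing (ChRO-seq), an assay that maps RNA polymerase engaged on chromatin by extending and sequencing nascent RNA, was performed on whole hearts of adult mice. Per the labels, the 10 samples comprised 4 Playrr mutant hearts, 4 wild-type hearts and 2 hearts labelled PHDHET, a term the labels do not explain. Heart tissue was cryopulverized before chromatin was extracted, per the labels' protocols.

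The data analysed here were 1 deposited table of peaks with 4 columns (chromosome, start, end and score) and no header. Its name identifies it as output of dREG, a caller that finds transcribed regulatory elements, meaning promoters and enhancers, from the pattern of nascent transcription on both strands. The deposited score is the authors' value from the caller for each peak. It is neither a read count nor a level in a sample, and it was used only to describe, rank and filter peaks within this list. The genome build was mm10, per the submitters' processing notes. The aligner, the caller's version, its threshold and the libraries that entered the list are not given in the sources used here. The table had 0 columns of per-sample values. No comparison between genotypes, no replicate error and no sequencing depth were therefore obtained, and differences between wild-type, Playrr mutant and PHDHET hearts were not analysed here. The score threshold sets which weak elements are listed, so the absence of a peak was read as no peak in this list and not as absence of transcription. Because the libraries behind the list are not identified, a peak was not assigned to any genotype.

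Gene names and positions came from the RefSeq table of assembly GRCm38.p6, the assembly that mm10 represents. On the 21 chromosomes that held peaks it listed 49943 genes, of which 21887 were protein-coding. Used here, the table gave the lower and upper coordinate of each gene span but no strand, transcript starts, exons or untranslated regions. The design fixed before the data were examined was written for transcription start sites. It was applied to both ends of each gene span instead, so a gene-end peak lies at the annotated 5′ or 3′ end, and promoters inside a span were not counted as gene-end peaks. The number of start sites was replaced by the number of RefSeq transcripts, exon, intron and untranslated-region classes were replaced by inside or outside a gene span, and the planned motif test was not run.

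A gene had a gene-end peak when a peak overlapped the 500 bp on either side of either end. A peak was distal when it lay over 1000 bp from both ends of every annotated gene of any class, and it was assigned to the protein-coding gene with the nearest end. The territory of a gene was the stretch of chromosome nearer to its ends than to those of any other protein-coding gene. For distal peaks per list, outside gene spans meant outside the spans of protein-coding genes, so peaks inside lncRNA spans were kept. The location of peaks used the spans of all annotated genes instead. Before the data were examined, 24 gene lists (491 entries) were fixed, covering heart function, cell types of the heart, tissues other than heart and general programmes. All but 1 entry (Ahsp) matched a protein-coding gene, which left 490 entries and 447 distinct genes.

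The share of members with a gene-end peak was compared with that of all other protein-coding genes by two-sided Fisher's exact test, and 95% exact Clopper-Pearson intervals were computed. The median number of distal peaks per member was compared with 10000 random lists of the same size, matched on territory length in 20 bins, a permutation of list membership within bins that gave a two-sided p. The smallest p these random lists can give is 0.0002. Both families of p-values were adjusted over the 24 lists by the Benjamini-Hochberg method with a threshold of 0.05. The alternative distal test among genes with a gene-end peak left out the lists of tissues other than heart. Its p-values were adjusted over the remaining lists only. The median of each list's highest gene-end peak score was placed among 10000 random lists of genes with a gene-end peak, matched on the transcript class (at most 1, 2 to 3, 4 or more). Intervals and p-values describe genes within 1 peak list. Genes are not independent replicates, and variation between animals enters none of these tests.

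Peak locations were compared with 100 random placements of the same peaks on the same chromosomes, without a mask for unmappable sequence. Median scores and widths were compared by a two-sided permutation test with 100000 resamples. Peaks at most 10 kb apart were joined into runs. Peaks in the Pitx2 interval were compared with 10000 random autosomal intervals of the same length.

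The rule for named genes was also fixed before the data were examined. It took Pitx2, Playrr and the protein-coding genes within 1 Mb of Pitx2. From each list it took up to 4 members with the highest gene-end score, the first 3 members in alphabetical order without a gene-end peak, and the 2 members with most distal peaks. Over the genome it took the 10 genes with the highest gene-end score, the 10 with most distal peaks and the 10 longest runs by peak count. The text names a subset of these. Alternatives comprised stricter score thresholds, other windows around gene ends, other definitions of a distal peak, other joining distances and matched backgrounds. The alternative restricted to the 5′ end of the gene could not be run without strand.

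The list tests were checked on simulated peaks laid on the 21887 protein-coding genes. In simulated lists of 20 genes, 3 of the 4 lists with a raised share of gene-end peaks and 4 of the 4 with a lowered share were found, with 0 of the 16 other lists called. The check had first required all 4 raised lists, and this was eased to 3 after that result. All 4 lists with added distal peaks were found, with 0 of the 20 others called. The simulated changes were large and set alike for all members of a list. The check therefore does not give the power to find smaller ones. Background peaks were placed evenly at random and the simulated lists were drawn at random. The real peaks are clustered, so the check does not give the rate of false calls on them. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.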

Results

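Transcribed regulatory elements were catalogued in whole adult mouse hearts in a series built around Playrr, a long noncoding RNA transcribed from the chromosome 3 locus of the transcription factor gene Pitx2. The samples comprised 4 Playrr mutant, 4 wild-type and 2 PHDHET hearts. A single list of 52257 peaks represented the series, so the values below describe the list as a whole, without replicate error, and genotypes were not compared. Peaks lay on 21 chromosomes, did not overlap and covered 20.4 Mb. Their median width was 370 bp (quartiles 290 and 470 bp), and their median dREG score, the caller's own value for each peak, was 0.600 (quartiles 0.437 and 0.831, range 0.256 to 1.58). Of the gaps between neighbouring peaks, 9298 (17.8%) were exactly 20 bp long. Joining peaks at most 100 bp apart left 42458 elements.

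The Pitx2 locus was examined first because the series concerns it. Pitx2, the homeobox gene of left-right patterning and atrial identity, carried a peak at its lower-coordinate end (chromosome 3, 129199711 to 129199990, mm10) with a score of 0.669, higher than 58.2% of all peaks. A pair of adjacent peaks lay inside the Pitx2 span at 129213651 to 129214020 (score 0.679) and 129214041 to 129214310 (score 0.525), 5574 and 5284 bp from its nearest end. Playrr (D030025E07Rik, 128117015 to 128231605, a lncRNA span of 115 kb) carried 0 peaks within its span or within 500 bp of it. Between the nearest protein-coding genes on either side, Fam241a and Enpep, an interval of 1.37 Mb held 6 peaks. The other 3 were 1 at the end of Fam241a and a pair at 127913921 to 127914180 and 127914201 to 127914660 (scores 0.552 and 0.787), which lay 1991 and 1511 bp from the lncRNA 9830132P13Rik. The 1.29 Mb from 127914661 to 129199710, which contains all of Playrr, held no peak.

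**Figure D1:**
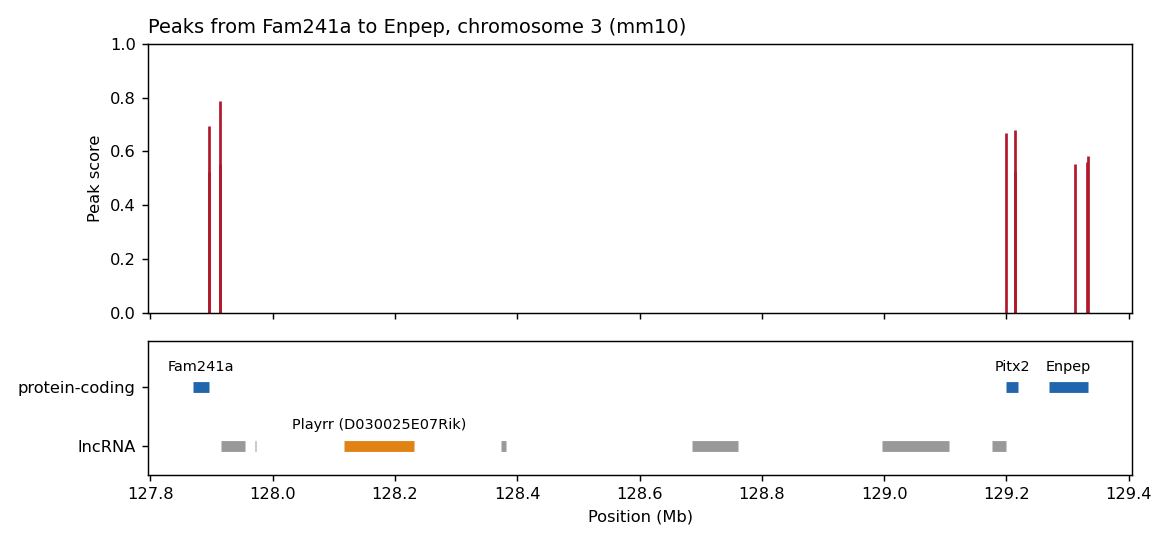
Peak scores (vertical axis, no unit) along chromosome 3 in Mb (horizontal axis, mm10) from Fam241a to Enpep, each vertical line a peak, above the spans of protein-coding genes (blue) and lncRNAs (grey, Playrr in orange). Peaks stand at Fam241a, beside it, at and inside Pitx2 and at Enpep, and none lies over Playrr.

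The density of peaks at the locus was not low for a region with few genes. Of 10000 random autosomal intervals of 1.37 Mb, 26.5% held no more than 6 peaks, with a median of 21. Among the 868 of these that contained the ends of 1 protein-coding gene, the median was 1 peak and 85.5% held no more than 6. With adjacent peaks joined, a choice made after the data were seen, the interval held 3 elements. The peak at Fam241a then joined a neighbour inside that gene, which moved its centre out of the interval and left the pair beside Fam241a, the peak at the end of Pitx2 and the pair inside Pitx2 as the 3 elements. Within 1 Mb of Pitx2, gene-end peaks marked Enpep (score 0.583), the fatty acid elongase gene Elovl6 (0.530), the growth factor gene Egf (0.825), Gar1 (1.05), Cfi (0.587), Pla2g12a (0.921), Casp6 (0.692), Mcub (0.731) and Col25a1 (0.605). Sec24b had 3 peaks in its span but none at a gene end, while Lrit3 and Rrh had 0 peaks in their spans.

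Gene ends across the genome were then compared with chance to find where the elements lay. Of all peaks, 36.8% (Wilson 95% interval 36.4 to 37.2%) lay within 500 bp of an annotated gene end, against 4.65% (range 4.47 to 4.92%) in 100 random placements, a 7.91-fold excess. Peaks elsewhere in a gene span made up 43.8% and peaks outside gene spans 19.4%, against 45.9% and 49.5% in random placements. Shifting every peak by 100 kb, which keeps their regional clustering, left 7.40% near gene ends, a 4.97-fold excess. Peaks near gene ends had a median score of 0.739, and the 29027 distal peaks one of 0.541. The difference of 0.198 passed a two-sided permutation test (p = 1e-05, the smallest it can give). Median widths were 390 and 360 bp (p = 1e-05, permutation test), a difference that was 0 among the 26129 peaks with the higher scores.

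Of 21887 protein-coding genes, 12072 (55.2%) had a gene-end peak, and 723 (3.30% of all protein-coding genes) had one at both ends. The 10 highest-scoring were Aig1 (1.43), the histone chaperone gene Asf1a (1.42), the protein C receptor gene Procr (1.37), Ppp1r8 (1.37), the CCAAT-binding factor gene Nfyb (1.37), Cul7 and Mrpl2 (1.34, a peak they share), Tsnax (1.34), Cbfb (1.34) and Trim44 (1.33).

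Gene lists of heart function were compared with all other protein-coding genes to ask which programmes carried elements at their gene ends. Calcium handling genes carried a gene-end peak in 19 of 20 cases (95%), led by Asph (score 1.17), the sodium-calcium exchanger gene Slc8a1 (1.14), the sodium pump subunit gene Atp1a2 (1.08) and the sarcoplasmic calcium pump gene Atp2a2 (1.07). Genes of the contractile apparatus did so in 25 of 28 cases (89.3%), among them the atrial myosin light chain gene Myl7 (1.11), Xirp2 (1.08), the myosin-assembly gene Smyd1 (1.06) and the tropomyosin gene Tpm1 (1.04). The 3 without one, Ldb3, Myl4 and Nebl, held 15, 12 and 4 peaks within their spans. Oxidative and fatty acid metabolism genes reached 33 of 34 (97.1%), with Ppara, the nuclear receptor that controls fatty acid oxidation, at 1.05 and the lipoprotein lipase gene Lpl at 1.04. Hadha and Hadhb, which encode the trifunctional protein of beta-oxidation, stood at 1.02, a peak they share. Without peaks shared between genes, 27 of the 34 had a gene-end peak. All 3 lists exceeded the share of about 55.1% among other protein-coding genes by Fisher's exact test (adjusted p = 0.00045, 0.000467 and 1.51e-06). That share, used for every list, is lowered by large families with few gene-end peaks. Among them are olfactory receptor genes (3 of 1110), vomeronasal receptor genes (1 of 355) and genes named Gm (133 of 1329). The lists were not compared with genes outside these families, which matters most for the smaller excesses. The stress and fetal gene programme reached 14 of 16 (87.5%, adjusted p = 0.0135, Fisher's exact test), with the natriuretic peptide genes Nppa (1.21) and Nppb (1.16), Mt1 (1.16) and Ankrd1 (1.14). With peaks counted anywhere in the gene span, an alternative chosen after the data were seen, the stress programme did not pass (22.9 points, adjusted p = 0.0703, exact test). Acta1, the skeletal alpha-actin gene, and Spp1 had 0 peaks in their spans.

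Rhythm and regulator genes had intermediate shares. Ion channels and gap junctions of heart rhythm carried gene-end peaks in 27 of 34 cases (79.4%, adjusted p = 0.00757, Fisher's exact test), led by the connexin 43 gene Gja1 (1.20), the L-type calcium channel gene Cacna1c (1.16), Cacna2d1 (1.15) and the inward rectifier gene Kcnj2 (1.02). Scores were lower at the sodium channel gene Scn5a (0.506) and the pacemaker channel gene Hcn4 (0.386), whose peak was shared with Rec114; these 2 fall outside the naming rule and were chosen after their values were seen. Hcn2 had 0 peaks in its span. The list's excess was no longer past the threshold when only the 39193 peaks scoring at least 0.437 were kept (18.6 percentage points, adjusted p = 0.0507, Fisher's exact test). Cardiac transcription factors reached 25 of 32 (78.1%, adjusted p = 0.0146, exact test), with Tbx3 (1.08), Tbx20 (1.06), Tbx18 (1.05) and Meis1 (1.04) highest. Irx4, a ventricular factor, had 2 peaks within its span and none at a gene end, and Hand1 had none at all. Genes near human atrial fibrillation variants reached 27 of 35 (77.1%, adjusted p = 0.0135, exact test), including Nppa (1.21), Cav2 (1.21) and Gja1 (1.20). That list shares 9 members with the ion channels and 7 with the transcription factors, and against random lists matched on transcript class its excess of 17.1 points did not pass (adjusted p = 0.0707, permutation test). Autonomic signalling (14 of 18), atrial markers (11 of 15) and ventricular markers (10 of 12) were not past the threshold (adjusted p = 0.0718, 0.21 and 0.0889, exact test). These calls turned on the setting. Without shared peaks all 3 lists passed (adjusted p = 0.0325, 0.0366 and 0.0114, exact test), but their counts did not rise. The counts were then 13 of 18, 11 of 15 and 10 of 12, while the comparison share fell from about 55.1% to 44.5 to 44.6%.

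**Figure D2:**
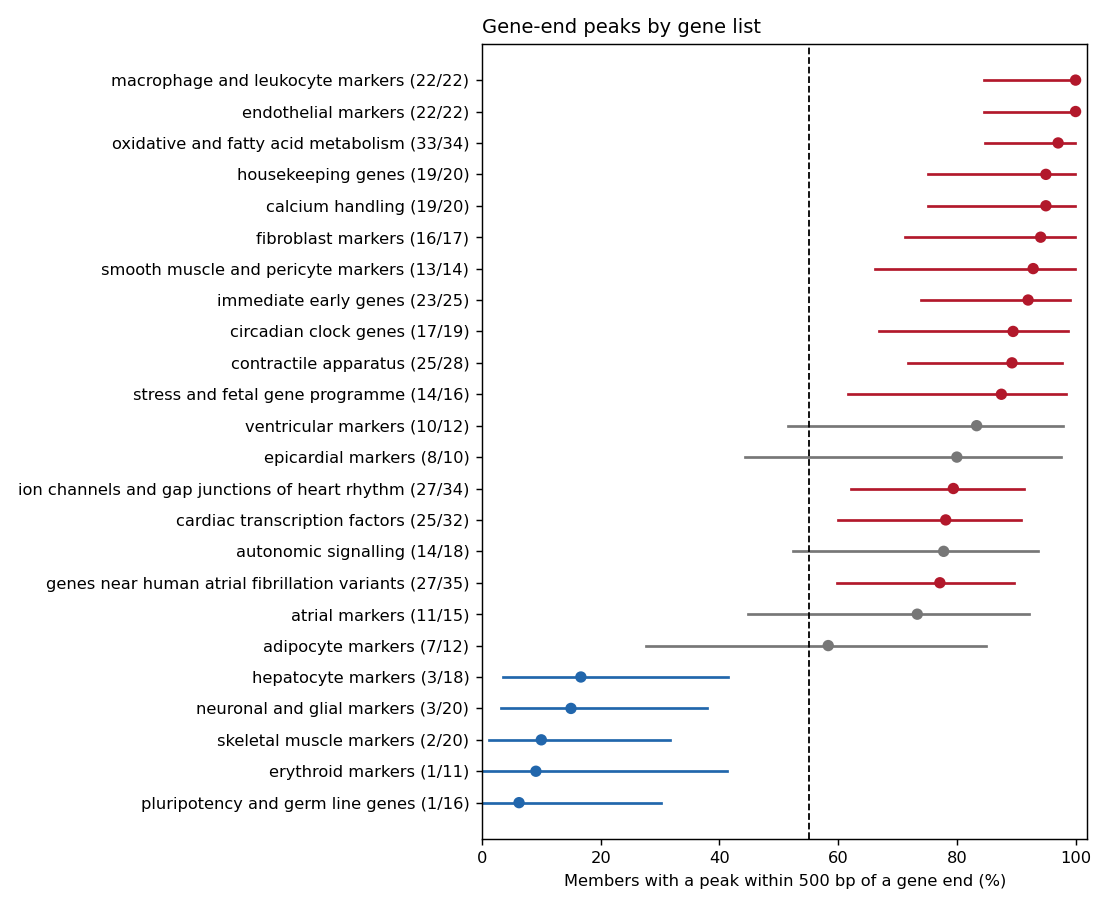
Percentage of the members of each gene list with a peak within 500 bp of a gene end (horizontal axis), with exact 95% intervals for counting error only, and counts in parentheses. The dashed line is the 55.2% of all protein-coding genes, red and blue lists were higher and lower at an adjusted p below 0.05, and grey lists were not past it.

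Markers of the cell types that a whole heart contains were also represented. All 22 endothelial markers carried a gene-end peak, with the angiopoietin-pathway receptor gene Tie1 (1.09), the tight-junction gene Cldn5 (1.07), the VEGF receptor gene Flt1 (1.04) and Fabp4 (1.01) highest. All 22 macrophage and leukocyte markers did so as well, with the scavenger receptor gene Cd163 (1.09) and the complement gene C1qa (1.06) highest (adjusted p = 2.12e-05 for either list, Fisher's exact test). Fibroblast markers reached 16 of 17, led by the fibronectin gene Fn1 (1.16) and the decorin gene Dcn (1.07), and smooth muscle and pericyte markers 13 of 14, led by the potassium channel gene Kcnj8 (1.10) and the smooth muscle actin gene Acta2 (1.08) (adjusted p = 0.0019 and 0.00757, Fisher's exact test). The smooth muscle excess did not pass with only the 39193 peaks scoring at least 0.437 (26.6 points, adjusted p = 0.0758, exact test). Tagln was the smooth muscle marker without a peak in its span. Epicardial markers (8 of 10) and adipocyte markers (7 of 12) were not past the threshold (adjusted p = 0.21 and 1, exact test). Epicardial markers passed over whole spans (10 of 10, adjusted p = 0.0215) and without shared peaks (8 of 10, adjusted p = 0.0325, exact test). The comparison shares there were 64.6% and 44.6%.

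Genes of other tissues carried few elements. Skeletal muscle markers had a gene-end peak in 2 of 20 cases (10%), Mylpf (0.920) and Actn3 (0.767), hepatocyte markers in 3 of 18, namely Ahsg (0.911), Foxa2 (0.845) and Apoa1 (0.326), and neuronal and glial markers in 3 of 20, namely Tubb3 (0.747), Olig1 (0.545) and Gfap (0.366). Erythroid markers had 1 of 11, the erythropoietin receptor gene Epor (0.447), and pluripotency and germ line genes 1 of 16, Sox2 (1.11). All 5 lists were below other protein-coding genes by Fisher's exact test (adjusted p from 0.000242 to 0.00612). Of the 5 lists, 13 neuronal, 12 hepatocyte, 14 skeletal muscle, 9 erythroid and 13 pluripotency or germ line genes had 0 peaks anywhere in their spans, among them the albumin gene Alb, Gad1, Gata1 and Myf5.

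General programmes were close to complete. Housekeeping genes reached 19 of 20, immediate early genes 23 of 25 and circadian clock genes 17 of 19 (adjusted p = 0.00045, 0.00045 and 0.00386, Fisher's exact test). Nr4a1, an immediate early nuclear receptor gene, had the highest gene-end score of any list member named here (1.24), followed in its list by Maff (1.19), Klf2 (1.14) and Klf4 (1.10). Among clock genes Nr1d2 (1.09), Clock (1.05) and Per2 (1.05) led, while Arntl, which encodes Bmal1, had 5 peaks in its span and none at a gene end. In total 14 lists were higher, 5 lower and 5 not past the threshold.

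Gene-end peaks were then described by the caller's score, which is not a level of transcription in a sample. The median score of immediate early genes was 0.999 (SD 0.158 over 23 genes) and lay at percentile 99.7 of matched random lists, whose median was 0.872. Macrophage and leukocyte markers had a median of 0.744 (SD 0.223 over 22 genes, percentile 2.30), and adipocyte markers one of 0.585 (SD 0.211 over 7 genes, percentile 1.21). Contractile genes (0.858, percentile 39.2) and housekeeping genes (0.867, percentile 47.7) lay near the middle. No list passed the threshold on this measure after adjustment, and 3 of 24 had an unadjusted permutation p below 0.05.

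Distal peaks were counted per gene to ask which programmes were surrounded by further elements. Immediate early genes had a median of 6 distal peaks per member (mean 8.72, SD 7.51, 25 genes), and a mean 6.23 times that of random lists matched on territory. Klf6 had 29 and Fos, a subunit gene of AP-1, had 21. Autonomic signalling genes had a median of 7 (mean 8.5, SD 6.36, 18 genes), with 22 at the phosphodiesterase gene Pde4d and 20 at the muscarinic receptor gene Chrm2. Endothelial markers had a median of 5, with 32 at the transcription factor gene Ets1 and 21 at Pecam1. Circadian clock genes also had a median of 5, with 26 at Rora and 11 at Nfil3. Cardiac transcription factors had a median of 4.5, with 22 at Mef2c and 20 at Gata4, against a median of 1 in their matched lists. Each of these 5 lists exceeded its matched random lists (adjusted p = 0.00048, permutation test with 10000 random lists, from the smallest p they can give). The clock gene call ended when only peaks over 5 kb from gene ends were counted (adjusted p = 0.126, permutation test), and those of clock genes and autonomic signalling ended by the mean outside gene spans (0.156 and 0.142).

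Contractile genes, genes near atrial fibrillation variants and atrial markers each had a median of 4 distal peaks, and calcium handling genes one of 3.5, with the same adjusted p of 0.00048 (permutation test). Actn2 and Ldb3, which encode Z-disc proteins, had 14 each, Slc8a1 had 17, Camk2d had 15 and Gja1 had 18. Stress programme genes had a median of 2.5 (adjusted p = 0.00048, permutation test), smooth muscle and pericyte markers one of 3 (0.000873), macrophage and leukocyte markers one of 1.5 (0.0044), fibroblast markers one of 4 (0.0181) and ion channels one of 2 (0.0309). The calcium handling call ended over 5 kb from gene ends (adjusted p = 0.0838), the smooth muscle call within 50 kb of them (0.0618) and the atrial call among genes with a gene-end peak (0.178, permutation test). The fibroblast call ended with the 39193 peaks scoring at least 0.437, over 2 kb and over 5 kb from gene ends, and the ion channel and macrophage calls ended when means were compared. An alternative chosen after the data were seen left out peaks inside the spans of protein-coding genes. The median was then 0 for contractile, calcium handling and ion channel genes and for their random lists alike. Their means there were 1.04, 1.55 and 1.06 against 0.464, 0.650 and 0.794, and none passed (adjusted p = 0.220, 0.220 and 0.699, permutation test). By the same mean the atrial fibrillation list (0.156), atrial markers (0.146), smooth muscle markers (0.315), macrophage markers (0.142) and fibroblast markers (0.0520) did not pass either. By the median outside spans these 5 lists did pass (adjusted p = 0.0171, 0.0449, 0.0317, 0.0012 and 0.0130, permutation test). Their medians there were 0.5 to 2, against random medians of 0. Metabolic genes had a median of 1 (adjusted p = 0.0867, permutation test), although 28 distal peaks were assigned to Ppargc1a, the coactivator of mitochondrial biogenesis, and their mean of 3.71 exceeded the matched lists (adjusted p = 0.00137, permutation test). Outside gene spans their mean was 1.15 against 0.441 and did not pass (adjusted p = 0.142, permutation test). Housekeeping genes had a median of 0 distal peaks (adjusted p = 1, permutation test). Their mean of 1.5 against 0.650 did not pass (adjusted p = 0.128), but they passed within 50 kb of gene ends (0.0278) and by the mean outside gene spans (1.2 against 0.2, adjusted p = 0.0307, permutation test). Ventricular (median 1), epicardial (median 1) and adipocyte (median 0.5) markers and the 5 lists of other tissues (median 0) were also not past the threshold. In total 14 lists were higher by the median and 13 by the mean. Outside gene spans 11 of the 14 stayed past the threshold by the median. By the mean only 5 passed there, namely immediate early genes, endothelial markers, cardiac transcription factors, the stress programme and housekeeping genes. The random lists stayed matched on whole territory and not on its part outside spans, which favours lists of short genes. A shortage of distal peaks could not have been found by the median, because every list's random medians reached down to 0.

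**Figure D3:**
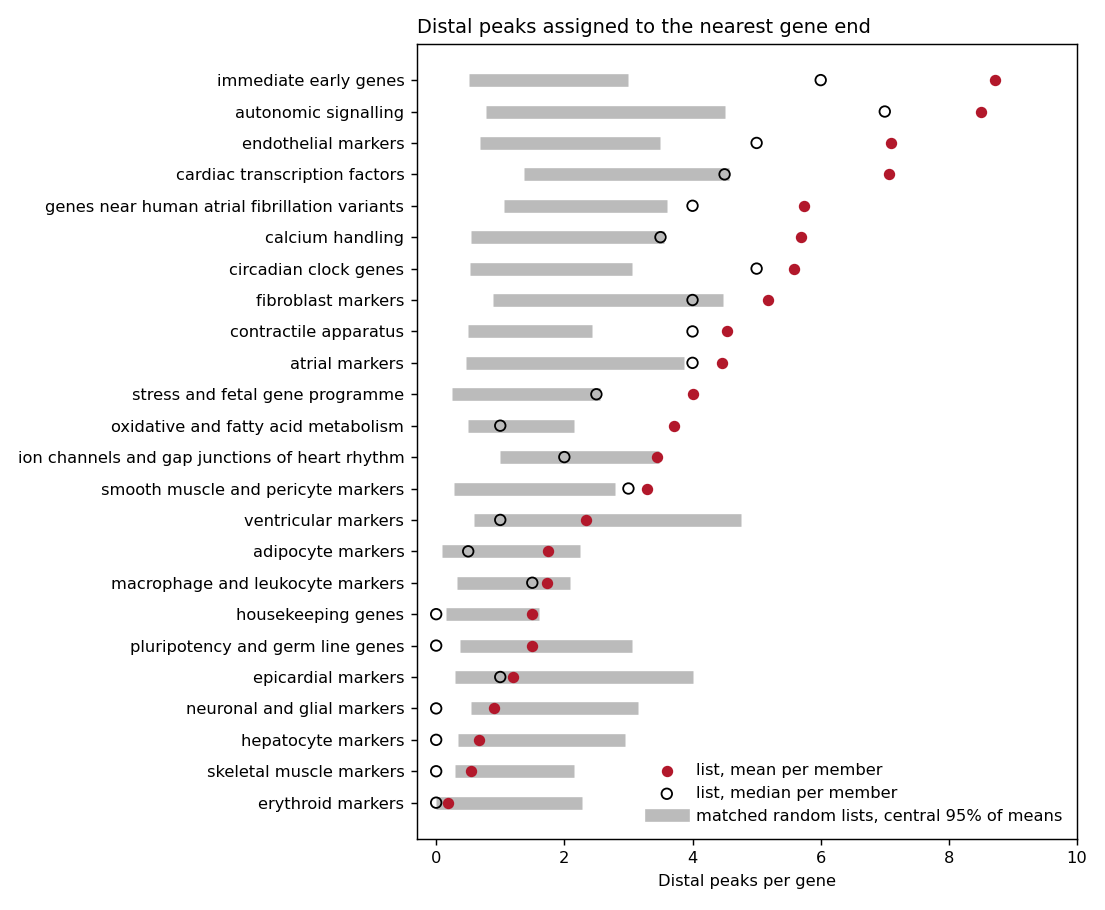
Number of distal peaks per gene (horizontal axis) for each gene list, as the mean (filled) and the median (open circle) over its members, with grey bars for the central 95% of means of 10000 random lists matched on territory. The mean of immediate early genes, 8.72, lies far to the right of its bar, whereas that of erythroid markers, 0.182, lies inside.

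Over the genome, distal peaks were most numerous for Rad51b (62), Lpp (48), Irf2bp2 (37), Tcf4 (37), Zfp36l2 (35), Tomm20 (33), Akap13, Bcor, Ets1 and Pakap (32 each). Assignment was by distance to a gene end alone. Peaks at most 10 kb apart formed 22352 runs, of which 10496 were single peaks and 341 held 10 or more peaks (8.53% of all peaks). At most 1 run of 10 or more formed in each of 100 random placements. Those placements spread peaks evenly over whole chromosomes, so they do not show clustering beyond that at genes. The run with most peaks held 37 over 119 kb of chromosome 1 (155027561 to 155146940) and overlapped the immediate early response gene Ier5 and Mr1. Next came 36 peaks over 98.0 kb of chromosome 15 at Nr4a1, Atg101 and Smim41, 34 on chromosome 9 across a gene-dense stretch from Tmem115 to Gnai2, and 31 on chromosome 2 (30652421 to 30726120), where no protein-coding gene was overlapped but noncoding genes such as 9330198N18Rik were. A run of 30 peaks over 70.3 kb of chromosome 14 (54924561 to 54994830) spanned the adjacent cardiac myosin heavy chain genes Myh6 and Myh7 with Mhrt, Mir208a and Mir208b, and also overlapped Efs, Il25 and Cmtm5. The others of the first 10 lay at Synpo (30), Irf2bpl (28), Klf13 (26), Midn (25) and Btg2 (22). The number of runs of 10 or more depended strongly on the settings. It was 14 with the 26129 higher-scoring peaks, 111 and 823 with joining distances of 5 and 20 kb, and 138 when peaks at most 100 bp apart were first joined.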

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

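Alternatives were fixed before the data were examined, except 6 kinds chosen after seeing the data: peaks anywhere in the gene span, shared peaks left out, peaks joined, comparison among genes with a gene-end peak, and peaks inside genes left out, by the median or by the mean. No paired analysis was possible because the peak list has no sample columns, and no replicate could be left out for the same reason. The motif test and the 5′-end alternative were not run. Depth is unknown, so what the list misses at low transcription was not measurable. Values are differences from the comparison genes or random lists, and the cause of a change was not tested unless the setting itself gives it. For gene-end peaks (percentage points), the ion channel excess was not past the threshold with the 26129 higher-scoring peaks (15.5) or the 39193 peaks scoring at least 0.437 (18.6). The atrial fibrillation list ended with the 26129 peaks (16.6) and with matched transcripts (17.1), smooth muscle with the 39193 peaks (26.6) and the stress programme over whole spans (22.9). Autonomic signalling passed within 1000 bp (31.2), over whole spans (35.4) and without shared peaks (27.7). Atrial markers passed over whole spans (35.4) and without shared peaks (28.8), epicardial markers likewise (35.4 and 35.4), and ventricular markers without shared peaks (38.8). Without shared peaks the comparison share was lower, 44.5 to 44.6%, and none of these lists gained a member with a peak. Adipocyte markers, not called in any setting, changed sign to -21.3 with the 26129 peaks and -10.3 with the 39193. With windows of 250 bp or peak midpoints, every list kept its side of the threshold. For distal peaks (per member), ion channels ended over 5 kb (1), by the mean (1.44), among genes with a gene-end peak (1) and outside spans (0). Calcium handling ended over 5 kb (1) and outside spans (0), contractile genes outside spans (0), clock genes over 5 kb (1), and atrial markers among genes with a gene-end peak (2). Fibroblast markers ended with the 39193 peaks (2), over 2 kb (2), over 5 kb (2) and among genes with a gene-end peak (2.5). Smooth muscle ended within 50 kb of a gene end (2.5), and macrophage markers by the mean (0.773) and with joined peaks (1). Metabolic genes passed with the 39193 peaks (1), within 50 kb (2.5) and by the mean (2.56), adipocyte markers with the 26129 peaks (0.5) and housekeeping genes within 50 kb (2.5). Uncalled ventricular markers changed sign among genes with a gene-end peak (-0.5), and uncalled epicardial markers by the mean (-0.3). Outside spans by the mean, 5 lists were higher, against 13 by the mean with all distal peaks and 14 by the median. Of the 14, contractile genes (0.571), ion channels (0.265), calcium handling (0.9), autonomic signalling (1.56), the atrial fibrillation list (0.857), atrial (1.4), fibroblast (2.12), smooth muscle (0.571) and macrophage markers (0.818) and clock genes (0.947) ended, and housekeeping genes passed (1). The share of peaks near gene ends was 48.3% with the 26129 peaks, 41.6% with the 39193, 30.8% within 250 bp and 44.5% within 1000 bp, and that outside spans 17.0%, 18.4%, 20.7% and 18.1%. The excess near gene ends was 4.97-fold against shifted peaks. The width difference was 0 bp (permutation p = 1) with the 26129 peaks. Runs of 10 or more numbered 14 with the 26129 peaks, 125 with the 39193, 111 at 5 kb, 823 at 20 kb and 138 with joined peaks, against 341. The Pitx2 interval held 3 joined elements, the element at Fam241a being centred outside it.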

Other observations

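The comparisons of gene families, gene classes and chromosomes, and the tests without shared peaks, with joined peaks, among genes with a gene-end peak and outside gene spans by the median or the mean, and the division of the second pattern into parts by their outcome, were chosen after the data had been examined. So were the test of gene deserts and the direct comparisons between pairs of lists.

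Of 112 families of protein-coding genes sharing the letters before the first digit of their symbol, with at least 20 members each, 46 had a higher and 30 a lower share of gene-end peaks than other genes (Fisher's exact test, adjusted over the families). Among the higher ones, gene-end peaks marked Vps genes of vesicle sorting in 34 of 35 cases, Med genes of the Mediator complex in 29 of 30, Eif translation factor genes in 50 of 56 and Rab GTPase genes in 61 of 69. Zinc finger genes named Zfp reached 292 of 397 (73.6%, adjusted p = 5.79e-13, Fisher's exact test). Among the lower families, gene-end peaks marked 3 of 1110 olfactory receptor genes (Olfr), 1 of 355 vomeronasal receptor genes (Vmn), 0 of 29 Defa and 0 of 24 Mup genes. Reads that match several near-identical copies cannot be told apart in such families, and how the authors treated them is not given in the sources used here. For distal peaks, 2 families were higher and 18 lower than random lists matched on territory. The higher ones were the phosphodiesterase family Pde (mean 5.88 per gene, SD 6.80 over 26 genes, against 2.15, adjusted p = 0.0048) and the Cd antigen family (2.35, SD 4.09 over 100 genes, against 1.13, adjusted p = 0.00224), by the permutation test.

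Among other gene classes, 145 of 408 tRNA genes (35.5%), 2894 of 12727 lncRNA genes (22.7%), 145 of 1228 miRNA genes (11.8%) and 150 of 9944 pseudogenes (1.51%) had a peak within 500 bp of an end. Genes on the X chromosome had one in 377 of 966 cases (39.0%) and autosomal genes in 11690 of 20665 (56.6%, Fisher's exact p = 1.42e-26). Families with few gene-end peaks were not set aside in this comparison, and its p was not adjusted. The Y chromosome carried 7 peaks, of which those at Kdm5d (score 0.485), Eif2s3y (0.571), Uty (0.814), Ddx3y (0.973) and Gm52481 (0.406) lay within 500 bp of a gene end. Xist had a gene-end peak with a score of 0.629, so Y-linked and Xist elements stand in the same list. Contractile genes of the heart and skeletal muscle markers differed directly in their share of gene-end peaks (25 of 28 against 2 of 20, Fisher's exact p = 2.82e-08). Macrophage and leukocyte markers differed from erythroid markers likewise (22 of 22 against 1 of 11, Fisher's exact p = 1.19e-07). Each of these pairs set a list already called higher against one already called lower. Their unadjusted p-values therefore add no independent evidence. For atrial against ventricular markers the exact test gave p = 0.662 (11 of 15 against 10 of 12).

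The first pattern weighed was the contrast between lists in gene-end peaks. A higher number of annotated transcripts per gene does not account for it as a whole, since 18 of the 19 lists past the threshold stayed past it in the same direction against random lists matched on transcript class; the exception was the atrial fibrillation list. Peaks shared with the end of a neighbouring gene do not account for it either, since 19 of the 19 stayed past it without such peaks. That the lists differ because their genes differ in transcription in the adult heart remains a hypothesis that was not tested, because no expression values were used here. Promoter base composition also stayed untested without a genome sequence.

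The second pattern was the excess of distal peaks near immediate early, autonomic, endothelial and other lists. Splitting of elements by the caller does not account for it as a whole, since 13 of the 14 lists stayed past the threshold with adjacent peaks joined, all but macrophage and leukocyte markers. Against random lists of genes with a gene-end peak, 11 of the 14 lists stayed past the threshold. Immediate early genes had a median of 6 against 0 there (adjusted p = 0.00127, permutation test). A general surplus of distal peaks at such genes is argued against for these 11 lists, except cardiac transcription factors. This test left out the lists of other tissues, which have few such members, so its p-values were adjusted over fewer lists. The call for cardiac transcription factors (p = 0.0260, adjusted p = 0.0449, permutation test) may rest on that smaller family. For ion channels, atrial markers and fibroblast markers, of which 0 stayed past the threshold, a general surplus cannot be told apart. The excess of the median there went from 2 to 1 for ion channels (27 of 34 members left), from 4 to 2 for atrial markers (11 of 15) and from 3 to 2.5 for fibroblast markers (16 of 17). The fibroblast excess thus stayed nearly as large, and its lost call does not speak for the explanation. The random lists outside gene spans were matched on whole territory, which favours lists of short genes, so a pass alone decides nothing. Internal promoters counted as distal are argued against as the whole cause for immediate early genes. Their mean outside spans, 7.32, exceeded the central range of random means with all distal peaks counted (upper limit 3). For endothelial markers (3.55, limit 3.5), the stress programme (2.56, limit 2.56) and cardiac transcription factors (3.625, limit 4.56) it stays undecided. These 4 of the 14 lists stayed past the threshold outside gene spans by both the median and the mean. In these the excess of the median went from 6 to 4 for immediate early genes, from 5 to 2 for endothelial markers, from 3.5 to 3 for cardiac transcription factors and from 2.5 to 1 for the stress programme. By the median alone 11 of the 14 lists stayed past it, but the random median outside spans was 0 for every list, so a median of 0.5 or 1 sufficed, and the excess fell from 6.5 to 1.5 for autonomic signalling, from 5 to 1 for clock genes and from 3 to 0.5 for smooth muscle markers. By the mean, 0 of the other 10 lists stayed past it, which follows from how they were set apart and decides nothing. Ion channels and macrophage markers had not passed by the mean with all distal peaks either (adjusted p = 0.106 and 0.236, permutation test). The mean over that of random lists went from 2.26-fold to 3.25-fold for fibroblast markers, from 1.81 to 3.57 for macrophage markers and from 2.79 to 3.33 for atrial markers, on fewer peaks. Matching on whole territory can raise such a fold for lists of short genes. These lost calls therefore speak neither for nor against internal promoters. It went from 3.92 to 2.75 for autonomic signalling, from 3.79 to 2.64 for clock genes, from 2.75 to 2 for the atrial fibrillation list, from 3.63 to 2.23 for contractile genes, from 3.45 to 2.38 for calcium handling, from 2.88 to 2.33 for smooth muscle markers and from 1.72 to 1.33 for ion channels. Among members outside spans the SD was as large as the mean or larger in each of these lists. For these 10 lists, and for the peaks inside spans in general, internal promoters and elements in introns cannot be told apart because the gene table used here has no transcript starts. Induction of immediate early genes during collection of the hearts is a candidate explanation that was not tested, since no value per heart exists in the list.

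The third pattern was the low number of peaks in the gene desert between Fam241a and Pitx2 that holds Playrr. Leaving out 1 kb at either gene, this desert of 1.30 Mb held 2 peaks, or 1.54 per Mb. So few peaks are what gene deserts of this size usually show. Of the 257 other autosomal deserts of at least 1 Mb between protein-coding genes, 69.3% had a density as low or lower. Their median was 0.448 per Mb, and 111 of them held no peak. They were not screened for unmappable sequence and include chromosome starts, such as 249402 to 3153657 on chromosome 7 with 0 peaks. The 2 peaks of the Pitx2 desert lay beside Fam241a. The autosomes held 233 peak-free stretches as long as the 1.29 Mb over Playrr. Elements active in few cells of a whole heart, or in embryos only, and elements below the caller's threshold were not tested. Any effect of the Playrr mutation on the locus was not tested either, because the list does not separate genotypes.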
